A study of Homo sapiens with 6 samples.

How the data were processed

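RNA was taken from PANC-1 cells after 24 h with 20 µM Schisandrin B or with a vehicle of less than 0.1% DMSO, in 3 libraries per group made with a SMARTER mRNA-Seq kit. The deposited counts are whole numbers per Ensembl gene, in columns headed as counts. The authors also deposited FPKM values, scaled for gene length and library size, which were used here only in a check beside the counts. The authors' fold change is a ratio of Schisandrin B over vehicle, and the deposited log2 fold change is its logarithm. The deposited p-values, raw and adjusted, come from the authors' own comparison, whose test is not given in the sources used here. The submitters' processing notes name the builds GRCh38 and mm10. The aligner, the counting tool and the strand setting are not given in the sources used here, so genes that overlap another gene or resemble a paralog are uncertain. Of 58228 genes that share an Ensembl ID with GENCODE release 29 on GRCh38, 58165 (99.9%) overlap it in position.

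The library totals were 13656826, 14577016 and 18289410 counts in vehicle and 16045095, 14290665 and 13667700 in Schisandrin B. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Group and replicate followed the sample titles.

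Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 15773 of 63241, and libraries were scaled by TMM. Groups were compared by the two-sided quasi-likelihood F-test with robust dispersion, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM are TMM-scaled, shares of counts are of the library total, and 3 against 3 libraries allow an exact two-sided permutation p of no less than 0.1.

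Gene lists, 33 in number, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 between genes and a minimum of 5 tested members. Adjustment ran over the 32 lists tested. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera rests on the few residual degrees of freedom of 6 libraries and has little power. Fry tests whether the genes of a list move on balance in one direction and compares them with no other genes.

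Genes named in the text followed a rule. It took the 10 protein-coding genes with the largest log2 fold change in each direction, among those past the threshold with a mean of at least 2 CPM and no overlap between groups. It also took up to 4 members with the smallest adjusted p from each list that passed and from the ferroptosis and iron lists, and up to 2 from other lists. GPX4, SLC7A11, ACSL4, TFRC, FTH1, FTL, HMOX1, AIFM2, MKI67, CDKN1A and CCND1 were always included. Not all of these genes are named, and any gene outside the rule is said to have been chosen after its values were seen. The groups, tests, lists, this rule and 18 of 19 alternative settings were made before the data were examined.

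The method was tested on simulated counts with the same totals and dispersions. Of genes changed 2-fold, 87.1% of 62 were recovered, and of those changed 1.5-fold, 55.4% of 65, with 18 calls among 14609 unchanged genes. Of those changed 4-fold, 100% of 63 were recovered. The 18 false calls are also to be read against the recovered genes, of which they are a larger share. Far fewer genes were changed in the simulation than were called in the data, so these rates need not carry over. A simulated list of 30 genes raised 1.5-fold was called by camera, and none of 31 unchanged lists was. The simulated genes were drawn independently, so this cannot show false list calls that come from correlation between genes.

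The alternatives were other scaling factors (RLE, upper quartile, library totals), no low-count filter, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, a threshold of 0.01, removal of mitochondrial and ribosomal protein genes, and each library left out in turn. A correction for GC content and transcript length with splines of 4 degrees of freedom was added after seeing the data. Deviations of libraries with the same replicate number had correlations across genes of 0.0337, -0.0527 and -0.0113, and genes are not independent replicates, so libraries were not treated as paired. Figures were drawn with matplotlib 3.10.9.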

Results

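Gene expression was profiled by RNA sequencing in PANC-1, an established human pancreatic carcinoma line. Cells received 20 µM Schisandrin B, a lignan found in Schisandra fruit, or a vehicle with less than 0.1% DMSO, and RNA was taken after 24 h. Each group held 3 libraries. The series title asks whether the compound acts against proliferation through ferroptosis, a form of cell death that depends on iron and on the oxidation of membrane lipids. The vehicle libraries held 13656826, 14577016 and 18289410 gene counts, and the Schisandrin B libraries held 16045095, 14290665 and 13667700. Of 63241 genes in the table, 15773 had enough counts to be tested. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

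Libraries of one group resembled each other far more than libraries of the other group. Across the genes tested, which are not independent replicates, Pearson's r of log2 CPM (counts scaled to a common library size) was 0.986 to 0.988 within groups and 0.921 to 0.929 between groups. The first principal component carried 80.1% of the variance. Every pair of libraries in a group differed by more than counting noise, with a chi-square per gene of 3.86 to 6.43.

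Schisandrin B changed most of the genes that could be tested. Genes of DNA replication and mitosis fell, with UHRF1, a factor that maintains DNA methylation during replication, 10.0-fold lower. In camera with an estimated correlation the call of the replication list held (adjusted p = 0.0375) and that of the mitosis list did not (adjusted p = 0.123). Of the tested targets of the stress factor ATF4, 30 of 31 rose, and of the list of chaperones of the endoplasmic reticulum (ER) 22 of 23, with the chaperone HSPA5 6.04-fold higher. The calls of these 2 lists did not hold, at adjusted p = 0.123 with an estimated correlation for ATF4 targets and adjusted p = 0.168 with an estimated correlation for ER chaperones. In camera with its preset correlation both lists passed in 16 of 16 other settings. In edgeR's quasi-likelihood test at an adjusted p threshold of 0.05, 5527 genes were higher in Schisandrin B, 5546 were lower and 4700 passed in neither direction. TMM scaling centres the fold changes (median log2 fold change 0.0004), so the near-even split is no result of its own. All rises and falls are relative to the other genes, and a change in total RNA per cell would not be seen. With a limit of 2-fold added, 2331 were higher and 1380 lower, and among the fewer genes with at least 5 CPM in 3 libraries these counts were 1238 and 882. All 3 values of one group lay beyond all 3 of the other for 73.5% of the genes tested, where chance gives 10% for 3 against 3. Protein-coding genes split into 3999 higher and 5161 lower of 12472 tested, and long noncoding RNA (lncRNA) genes into 1263 higher and 198 lower of 2453.

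Among the protein-coding genes with the largest rises were KLHDC7B, CHST1, a carbohydrate sulfotransferase, LAMP3, a lysosomal membrane protein, KCP and INHBE, an inhibin subunit. KLHDC7B (ENSG00000130487, chromosome 22, 50545899 to 50551023 on GRCh38) had 3 counts in all vehicle libraries together and 2046 in all Schisandrin B libraries. That gave a ratio of count rates of 721 with an exact binomial 95% interval of 246 to 3499, which covers counting error only. LAMP3 rose from 0.591 ± 0.216 to 42.9 ± 2.18 CPM (SD, n = 3 each), a log2 fold change of 6.12 with a standard error (SE) of 0.16. KCP rose 60.3-fold and UNC5B, a netrin receptor, 33.8-fold. The largest falls were in ZNF488 at a log2 fold change of -5.86 (SE 0.40) and FAM111B at -5.52 (SE 0.21). ZNF488 had 7 counts in all Schisandrin B libraries together, and its log2 fold change was -7.76 without Schisandrin B replicate 1. E2F8 and E2F2, transcription factors of the E2F family, fell 20.5-fold and 14.2-fold. SPC24, a kinetochore protein, fell 17.4-fold and CDKN2C, an inhibitor of the G1 kinases, 16.9-fold. The adjusted p of these genes in edgeR's test was 2.53e-06 or smaller.

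Of the 33 gene lists fixed before the data were examined, 32 had at least 5 tested members. Camera, a competitive test of a list against the other genes, placed 8 lists higher, 8 lower and 16 in neither direction with its preset correlation. With a correlation estimated for each list, 2 of those 16 calls held, both in lists that were lower. These were G1/S with DNA replication and DNA damage repair with the ATR pathway, and the other 14 calls did not hold. The estimated correlation leaves the test few degrees of freedom, so a lost call is no evidence that a list did not shift. Counts of genes within a list are given over all genes tested. Adjusted over the list alone, they were the same in 31 of the 33 lists, and the exceptions are named with their lists.

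**Figure D1:**
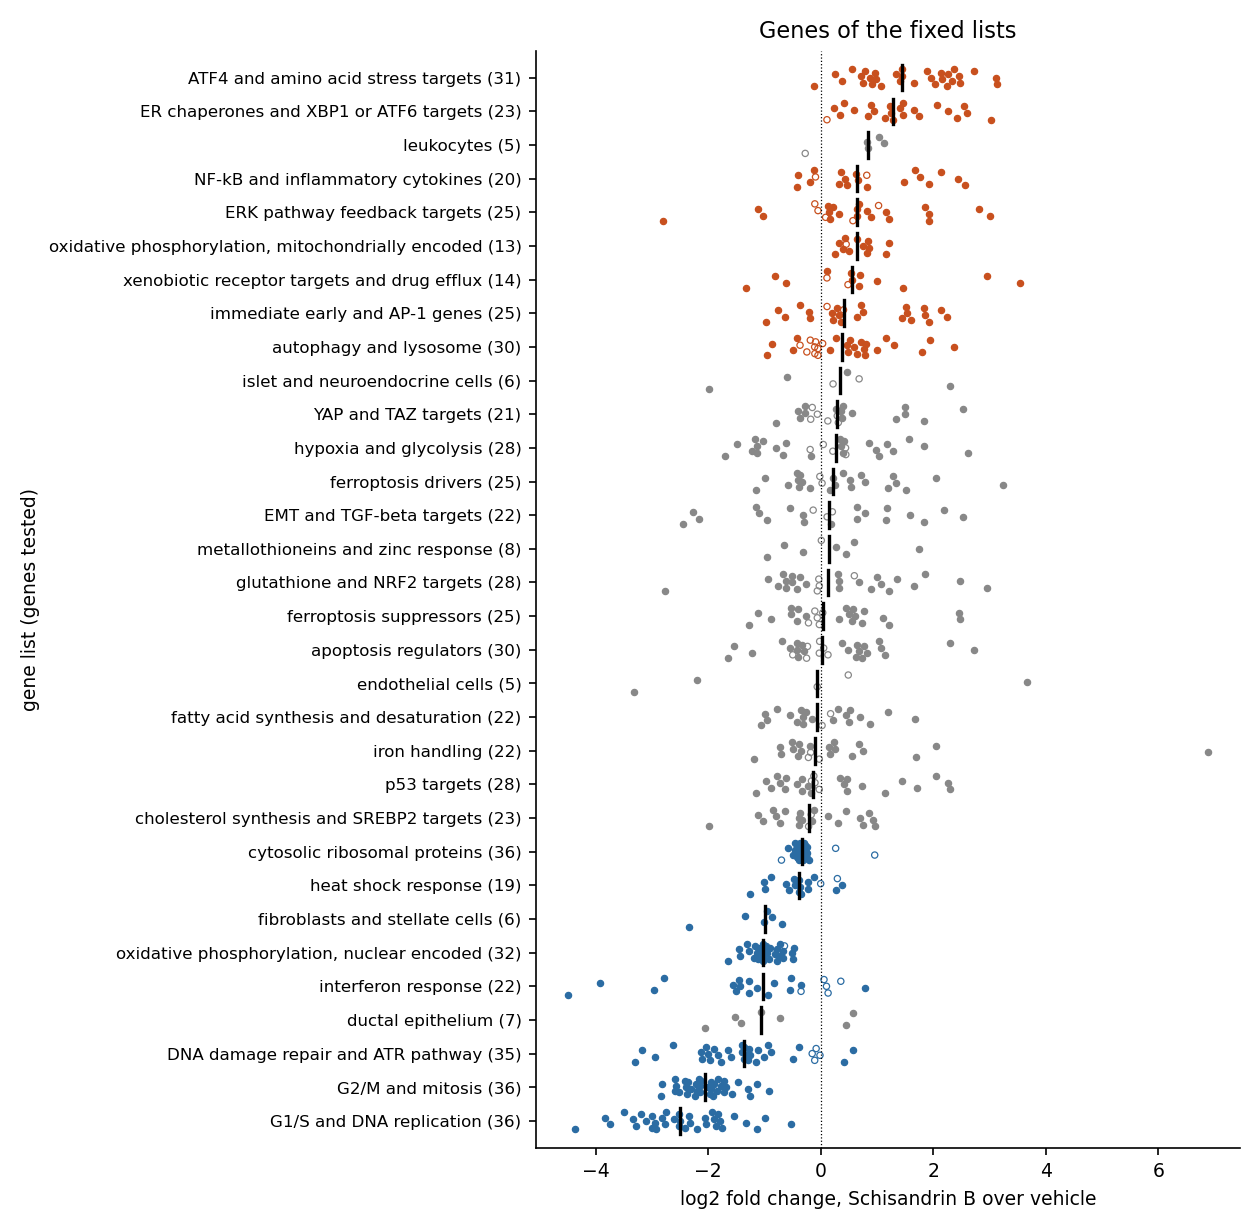
Log2 fold change of Schisandrin B over vehicle (horizontal axis) for each tested gene of the 32 lists (vertical axis, genes tested in brackets), with filled points past edgeR's threshold, open points not past it, black bars for medians, and lists called by camera orange (higher), blue (lower) or grey (neither). The G1/S list has the lowest median at -2.51 and the ATF4 list the highest at 1.44, and the point at 6.88 in iron handling is LCN2, whose fitted value depends on the prior count because it had no count in vehicle.

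The ferroptosis genes moved in both directions. GPX4, the selenoenzyme that reduces lipid hydroperoxides in membranes (ENSG00000167468, chromosome 19, 1103982 to 1106791 on GRCh38), fell from 264 ± 3.71 to 110 ± 3.13 CPM (SD, n = 3 each). Its log2 fold change was -1.27 (SE 0.04, adjusted p = 6.9e-14). The cystine transporter genes rose, with SLC7A11 going from 25.1 ± 1.41 to 141 ± 6.40 CPM, a log2 fold change of 2.48 (SE 0.06, adjusted p = 1.06e-15). SLC3A2, its partner chain, rose 5.51-fold. AIFM2, which protects membranes independently of GPX4, rose 2.14-fold, and the chaperone HSPB1 fell 1.85-fold. Among 25 suppressors of ferroptosis that were tested, 12 rose, 8 fell and 5 passed in neither direction, and the counts adjusted over the list alone were the same. The list median was 0.04 and its test found no shift against other genes (camera adjusted p = 0.527).

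Ferroptosis drivers were also divided. ACSL4, which loads polyunsaturated fatty acids into membrane lipids, rose from 104 ± 2.31 to 240 ± 5.95 CPM (SD, n = 3 each), a log2 fold change of 1.20 (SE 0.04, adjusted p = 1.64e-13). SAT1, an enzyme of polyamine breakdown, rose 9.40-fold, HMOX1, heme oxygenase, 4.15-fold and the amino acid transporter SLC38A1 2.85-fold. PEBP1, a scaffold for lipoxygenases, fell 2.23-fold. Of 25 drivers tested, 14 rose, 9 fell and 2 passed in neither direction, with the same counts adjusted over the list alone. The median was 0.23 and the list was not called (camera adjusted p = 0.263).

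**Figure D2:**
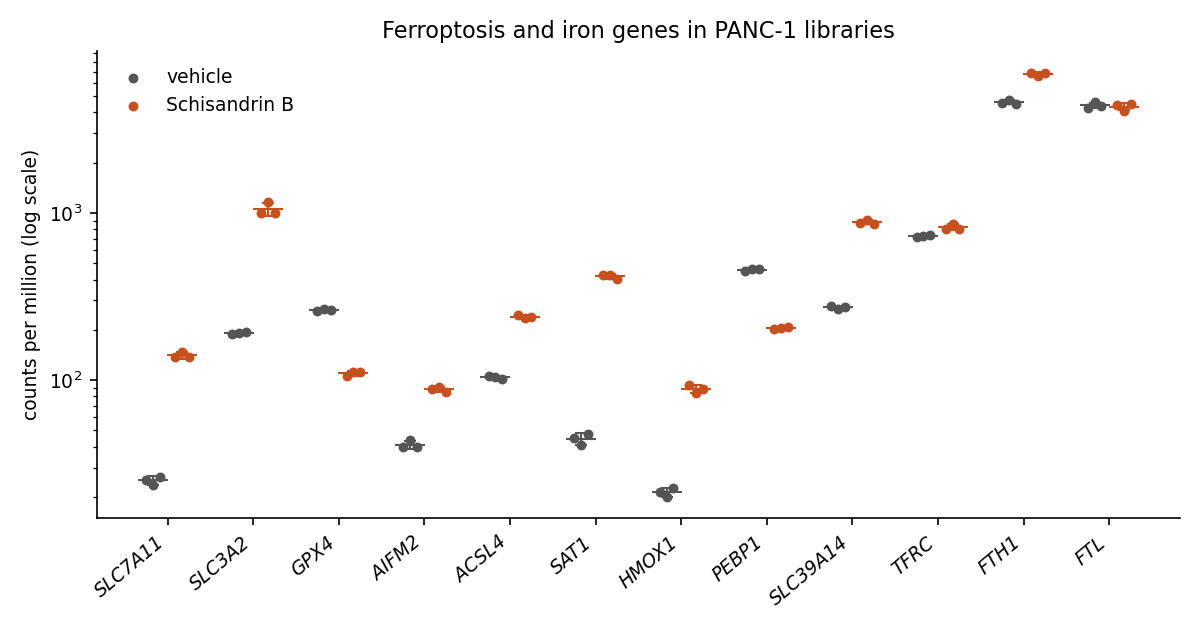
CPM on a log axis (vertical) for 12 ferroptosis and iron genes (horizontal) in the 3 vehicle (grey) and 3 Schisandrin B (orange) libraries, with points for libraries and bars for mean ± SD. GPX4 lies at 110 CPM against 264 in vehicle, SLC7A11 at 141 against 25.1, and the FTL points of both groups overlap.

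Iron genes showed no common direction. SLC39A14, a carrier of zinc and non-transferrin iron, rose from 273 ± 5.87 to 881 ± 26.9 CPM (SD, n = 3 each). FTH1, the ferritin heavy chain, rose 1.48-fold, and TFRC, the transferrin receptor, rose by a log2 fold change of 0.17 (SE 0.04, adjusted p = 8.79e-04). FTL, the ferritin light chain, stood at 4408 ± 171 and 4334 ± 223 CPM with an adjusted p of 0.629. Its log2 fold change of -0.02 turned positive under other settings, with values of 0.02 to 0.06. FECH, the last enzyme of heme synthesis, fell 1.62-fold. Of 22 iron genes tested, 10 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.904). The median of -0.10 lay below 0, while the mean of 0.37 and the test's direction lay above it. LCN2, named after its values were seen, had 0 counts in vehicle and 43 in Schisandrin B. Against a floor of 3 counts over the vehicle group it was 15.2-fold higher, which leaves out the counting error in Schisandrin B. With LCN2 at that value the list median was -0.10 and the mean 0.23. Without LCN2 the mean was 0.06.

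Glutathione and NRF2 target genes likewise split, with 13 higher and 11 lower of 28 tested, a count that was the same adjusted over the list alone. AKR1C1, an aldo-keto reductase, rose 3.61-fold, and NQO1, a quinone reductase often used to read NRF2 activity, fell 1.53-fold. AKR1C1 has near-identical family members that can share reads, so its value is uncertain. The list median was 0.14 and the list was not called (camera adjusted p = 0.67).

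Genes of cell division fell as a group. All 36 tested genes of G1/S and DNA replication fell, with a median log2 fold change of -2.51. MCM5 and MCM2, subunits of the replicative helicase, fell 9.76-fold and 5.75-fold, and RRM2, a ribonucleotide reductase subunit, fell from 219 ± 2.16 to 28.5 ± 1.70 CPM (SD, n = 3 each). All 36 tested genes of G2/M and mitosis fell as well, with a median of -2.06. TOP2A, a topoisomerase, fell from 528 ± 12.3 to 99.5 ± 3.91 CPM, and the proliferation marker MKI67 fell by 2.15 on the log2 scale (SE 0.05, adjusted p = 4.53e-16). CCND1, cyclin D1, fell 2.03-fold. Camera called both lists lower at an adjusted p of 7.23e-16, and the counts were the same adjusted over the list alone. The G1/S call held at adjusted p = 0.0375 with an estimated correlation, and the G2/M call did not (adjusted p = 0.123 with an estimated correlation). Before adjustment, camera with an estimated correlation gave p = 0.00155 for G1/S and p = 0.0262 for G2/M. That test has little power here, so it does not set the 2 lists apart.

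Genes of DNA damage repair and the ATR pathway fell in 29 of 35 cases and rose in 2, also adjusted over the list alone, with a median of -1.37 (camera adjusted p = 1.53e-08). CLSPN, the checkpoint mediator claspin, fell from 54.3 ± 2.58 to 5.50 ± 0.247 CPM (SD, n = 3 each). RPA1, a single-strand DNA binding protein, and FANCI, of the Fanconi pathway, fell 3.43-fold and 3.72-fold. The call held at adjusted p = 0.0375 with an estimated correlation.

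Targets of p53 did not move together. GADD45A and SESN2, stress genes, rose 3.27-fold and 4.80-fold, and CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 12.0 ± 2.39 to 16.8 ± 1.77 CPM (SD, n = 3 each), a log2 fold change of 0.47 (SE 0.14, adjusted p = 0.00651). In all, 11 of 28 tested targets rose and 12 fell, also adjusted over the list alone (camera adjusted p = 0.904). Here the median of -0.14 and the test's direction were negative while the mean of 0.20 was positive. Of 30 apoptosis regulators, 13 rose and 10 fell, with the same counts adjusted over the list alone, a median of 0.02 and a camera adjusted p of 0.631. TNFRSF10B, a death receptor for TRAIL, rose 4.94-fold and BCL2L1, which encodes the survival protein BCL-XL, rose 2.05-fold.

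The ATF4 list rose almost throughout. Of 31 tested ATF4 and amino acid stress targets, 30 rose and 1 fell, also adjusted over the list alone, with a median log2 fold change of 1.44. DDIT3, the stress factor CHOP, rose from 14.6 ± 0.864 to 97.1 ± 4.63 CPM (SD, n = 3 each). TRIB3, a pseudokinase, rose 4.45-fold and SLC7A5, a carrier of large neutral amino acids, 3.72-fold. SLC7A11 and SLC3A2 belong to this list as well as to the ferroptosis suppressors. Camera called the list higher at an adjusted p of 1.04e-11, which did not hold (adjusted p = 0.123 with an estimated correlation).

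ER chaperones and targets of XBP1 or ATF6 rose in 22 of 23 cases and none fell by the test. The median was 1.28, and the counts adjusted over the list alone were the same. HSPA5, the main ER chaperone, rose from 509 ± 8.03 to 3070 ± 170 CPM (SD, n = 3 each). XBP1 rose 4.78-fold, the cochaperone DNAJB9 8.12-fold and SEL1L, of ER-associated degradation, 3.34-fold. The camera adjusted p was 3.92e-09 (adjusted p = 0.168 with an estimated correlation).

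More heat shock response genes fell than rose. Of 19 genes tested, 15 fell and 2 rose, also adjusted over the list alone, with a median of -0.38. HSPE1, a mitochondrial chaperonin, fell 1.98-fold, and HSP90AA1, a cytosolic chaperone, fell from 2252 ± 80.4 to 1523 ± 58.3 CPM (SD, n = 3 each). The camera adjusted p was 0.00495 (adjusted p = 0.467 with an estimated correlation). Genes of autophagy and the lysosome rose in 17 of 30 cases and fell in 4, with the same counts adjusted over the list alone and a median of 0.37. MAP1LC3B, a component of the autophagosome membrane, rose from 220 ± 6.49 to 844 ± 41.4 CPM, and WIPI1 and GABARAPL1, also of the autophagy machinery, rose 3.47-fold and 2.48-fold. LAMP2, of the lysosomal membrane, rose 1.75-fold. The autophagy call rested on a camera adjusted p of 0.0357. It was lost without vehicle replicate 2 (0.0631), without Schisandrin B replicate 1 (0.0551), with DESeq2 (0.0671), with the replicate number as a block (0.0592) and with a correlation estimated from the data (adjusted p = 0.208 with an estimated correlation). It passed in 12 of 16 other settings with the preset correlation, with adjusted p from 0.00745 to 0.0671. With 1 library left out, the median ran from 0.21, without vehicle replicate 3, to 0.41.

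Nuclear and mitochondrial genes of oxidative phosphorylation moved apart. Of 32 nuclear-encoded genes, 31 fell and none rose, with a median of -1.02. ATP5F1B, a subunit of ATP synthase, fell from 914 ± 5.04 to 451 ± 3.84 CPM (SD, n = 3 each), and ATP5F1A and ATP5PB fell 2.03-fold and 2.04-fold. Of 13 mitochondrially encoded genes, 12 rose and none fell, with a median of 0.64. MT-ND4, a complex I subunit, rose 2.32-fold, MT-CO1, of complex IV, 1.81-fold and MT-CYB, of complex III, 1.42-fold. Camera called the nuclear list lower at an adjusted p of 8.78e-11 and the mitochondrial list higher at 0.00116, and the counts were the same adjusted over the list alone. Neither call held, at adjusted p = 0.123 with an estimated correlation for the nuclear and adjusted p = 0.518 with an estimated correlation for the mitochondrial list. Mitochondrial genes took 4.17 ± 0.288% of the counts in vehicle and 6.69 ± 0.465% in Schisandrin B (SD, n = 3 each). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows.

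Ribosomal protein genes fell slightly relative to the other genes. Of 36 tested, 33 fell and none rose, also adjusted over the list alone, with a median of -0.33 (camera adjusted p = 4.03e-06, adjusted p = 0.386 with an estimated correlation). RPS15 fell by 0.58 on the log2 scale (SE 0.04) and RPLP0 by 0.42 (SE 0.04). Ribosomal proteins have many processed pseudogenes, so single genes are uncertain. All ribosomal protein genes together took 6.00 ± 0.111% of the counts in vehicle and 4.91 ± 0.116% in Schisandrin B (SD, n = 3 each, exact permutation p = 0.1). lncRNA genes took 1.69 ± 0.0313% and 3.21 ± 0.12%, with the same p.

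**Figure D3:**
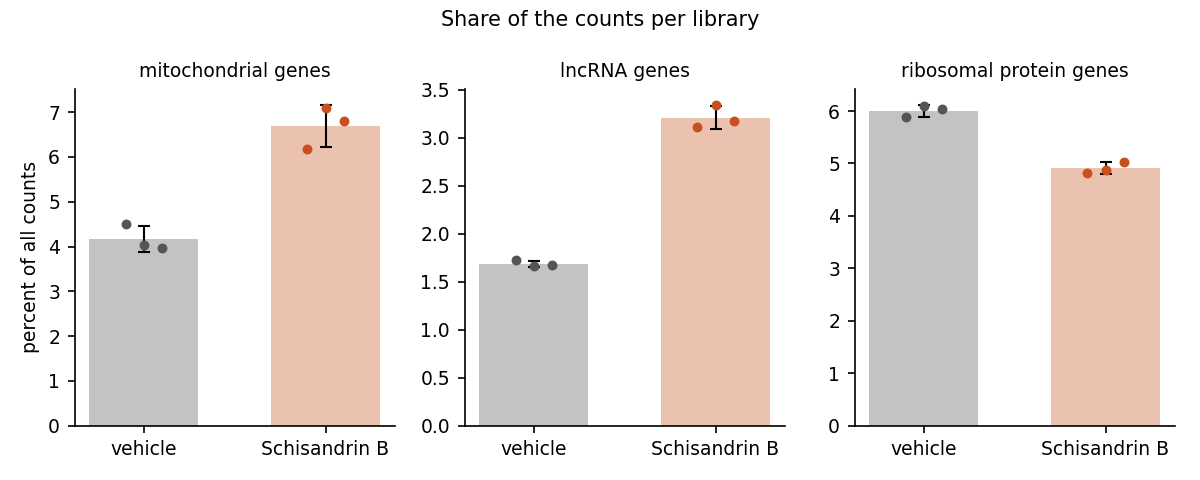
Percent of all counts (vertical axes, from 0) in mitochondrial, lncRNA and ribosomal protein genes, with bars for group means, whiskers for SD and points for the 3 libraries per group. The mitochondrial share was 4.17% in vehicle and 6.69% in Schisandrin B, the lncRNA share 1.69% and 3.21%, and the ribosomal protein share 6.00% and 4.91%.

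Lipid and sugar metabolism showed mixed responses. Of 23 genes of cholesterol synthesis, 8 rose and 13 fell, with a median of -0.21 (camera adjusted p = 0.352). ACAT2, a thiolase that feeds the sterol pathway, fell 3.96-fold and FDPS, farnesyl diphosphate synthase, 1.80-fold. Of 22 genes of fatty acid synthesis, 9 rose and 11 fell (camera adjusted p = 0.99), with a negative median of -0.06 and test direction beside a positive mean of 0.02. ACLY, which makes cytosolic acetyl-CoA, fell 1.98-fold. Of 28 genes of hypoxia and glycolysis, 12 rose and 11 fell, with a median of 0.28 (camera adjusted p = 0.904). That median ran from 0.15 to 0.30 with 1 library left out. HK2, hexokinase 2, rose 3.59-fold, whereas PKM, pyruvate kinase, fell from 1330 ± 19.7 to 571 ± 15.7 CPM (SD, n = 3 each). The counts of these 3 lists were the same adjusted over the list alone.

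More immediate early, ERK feedback and inflammatory genes rose than fell. In the AP-1 list 17 of 25 genes rose and 6 fell (median 0.41, camera adjusted p = 0.00566, adjusted p = 0.133 with an estimated correlation). ATF3, also an ATF4 target, rose 4.72-fold, and JUN rose 1.69-fold. Among ERK feedback targets 17 of 25 rose and 3 fell (median 0.64, camera adjusted p = 0.00286, adjusted p = 0.123 with an estimated correlation). The phosphatase DUSP5 rose 8.04-fold, and the growth factors HBEGF and AREG rose by log2 fold changes of 2.81 and 1.21. CCND1, a member of this list, fell. In the NF-kB and cytokine list 14 of 20 rose and 4 fell, and 15 rose and 4 fell adjusted over the list alone (median 0.65, camera adjusted p = 0.00314, adjusted p = 0.425 with an estimated correlation). The chemokine CXCL8 rose from 88.8 ± 5.08 to 483 ± 30.6 CPM (SD, n = 3 each), and IL1A and CXCL2 rose 4.38-fold and 5.89-fold. The AP-1 and ERK counts were the same adjusted over the list alone.

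Interferon response genes fell. Of 22 tested, 16 fell and 1 rose, also adjusted over the list alone, with a median of -1.03. IFIT1 fell from 19.6 ± 0.721 to 1.28 ± 0.234 CPM (SD, n = 3 each), and OAS3, an oligoadenylate synthase, fell 7.76-fold. The camera adjusted p was 0.00228 (adjusted p = 0.123 with an estimated correlation).

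Of 14 xenobiotic receptor targets and efflux pumps, 9 rose and 3 fell, also adjusted over the list alone, with a median of 0.55. The transporters ABCC3 and ABCC2 rose by log2 fold changes of 2.96 and 0.68, and CYP1B1, a cytochrome P450, rose 2.77-fold. The call was marginal at a camera adjusted p of 0.0466 (adjusted p = 0.208 with an estimated correlation). It passed in 6 of 16 other settings, with adjusted p from 0.0275 to 0.0772. It was lost without vehicle replicate 1 (0.0579), vehicle replicate 3 (0.0512), Schisandrin B replicate 1 (0.0551) or Schisandrin B replicate 3 (0.0603).

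The remaining response lists were not called. Of 22 genes of epithelial-mesenchymal transition (EMT) and TGF-beta signalling, 10 rose and 9 fell (median 0.15, camera adjusted p = 0.677). With 1 library left out, that median ran from 0.03 to 0.14. CCN2, a matricellular protein, rose 5.75-fold. Of 21 YAP and TAZ targets, 10 rose, among them the ectonucleotidase NT5E at 2.81-fold, and 5 fell (median 0.29, camera adjusted p = 0.215). Of 8 metallothionein and zinc genes, 4 rose and 3 fell (median 0.14, camera adjusted p = 0.8). The zinc exporter SLC30A1 rose 3.35-fold and the importer SLC39A10 fell 1.57-fold. Metallothionein genes resemble each other closely and are uncertain one by one. The counts of these 3 lists were the same adjusted over the list alone.

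Genes used as markers of cell types were measured as well. All libraries came from the PANC-1 line, so these genes do not measure amounts of other cell types. That also holds for the endothelial and leukocyte genes below. Of 7 ductal genes, 2 rose and 5 fell (median -1.06, camera adjusted p = 0.103). KRT8, a keratin, fell 2.67-fold and SOX9, a ductal transcription factor, 2.86-fold. All 6 tested fibroblast and stellate cell genes fell (median -0.98, camera adjusted p = 0.00381, adjusted p = 0.123 with an estimated correlation). Among them COL1A2 fell from 219 ± 8.67 to 43.2 ± 0.623 CPM (SD, n = 3 each) and RGS5 fell 2.53-fold. Of 6 islet and neuroendocrine genes, 2 rose and 2 fell, and 3 rose and 2 fell adjusted over the list alone (median 0.34, camera adjusted p = 0.904). The secretogranin SCG2 fell 3.96-fold. The acinar list had 2 tested members, under the minimum of 5 for a list test, and both rose, also adjusted over the list alone. CEL, a lipase, was at 1.11 ± 0.171 CPM in vehicle and 2.49 ± 0.708 in Schisandrin B. AMY2B, the other, was called at an adjusted p of 0.0207, which did not hold without vehicle replicate 2 (0.0916), without Schisandrin B replicate 2 (0.0775) or 3 (0.106), or with DESeq2 (0.125). Over 15 other settings its adjusted p ran from 0.00482 to 0.125.

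Of 5 endothelial genes, ROBO4 rose 12.6-fold, CDH5 fell from 12.9 ± 0.53 to 1.29 ± 0.378 CPM (SD, n = 3 each), and 1 rose and 2 fell in all (median -0.06, camera adjusted p = 0.8). With no low-count filter the endothelial median was -1.56, and the list passed in 0 of 15 other settings with adjusted p from 0.527 to 0.935. Of 5 leukocyte genes, 4 rose and none fell (median 0.85, camera adjusted p = 0.0957). CD68, used in tissue as a macrophage marker, rose 2.06-fold and CD8A 1.78-fold in this cell line. The leukocyte list passed its test without vehicle replicate 3 (0.0496), and its adjusted p over 15 other settings ran from 0.0496 to 0.409. The ductal, fibroblast, endothelial and leukocyte counts were the same adjusted over the list alone.

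The authors' deposited table marked 2526 genes as up and 1577 as down, with fold limits of 2 and an unadjusted p below 0.05. Of its marked genes, 2212 up and 1488 down also had an adjusted p under 0.05 in that table. GPX4 had a log2 fold change of -1.31 and SLC7A11 of 2.44 in the authors' deposited table, against -1.27 and 2.48 here. The deposited values differed from those here by a median of -0.0394, and so did those of the DESeq2 alternative. AMY2B had 1.256 both in the deposited table and with DESeq2. The DESeq2 alternative may therefore largely repeat the authors' comparison. Across 15773 genes, which are not independent replicates, the log2 fold changes in the authors' deposited table and those computed here had a Pearson r of 1.00. Both come from the same libraries, so the close match is a check of the computation and no independent support. Of 2114 genes marked up there and tested here, 2095 were higher at an adjusted p under 0.05, and of 1473 marked down, 1456 were lower.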

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

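The 3 tests of the GPX4 FPKM entry, the correction for GC content and transcript length, the test of the mitochondrial share and the selenoprotein list were chosen only after the results were seen.

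The deposited FPKM of GPX4 in Schisandrin B replicate 1 is 115801071, in a column that the comparisons did not use. The other 2 Schisandrin B libraries list 115 and 119 for this gene. The GPX4 counts were 1734 in that library against 1603 and 1546, and the CPM ratio to the mean of the other 2 was 0.959, which argues against abundance of the RNA. No other gene of 11105 compared was over 10-fold off in that column (count 0), which argues against another scale for the column. A missing decimal point may explain the entry: moved by 6 decimals, the most of any FPKM in the table, it is 116, or 1.07 per CPM, and the other 5 libraries have 1.02 to 1.07. No biological explanation was tested. The comparisons rest on counts and do not use this entry.

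GPX4 and the nuclear-encoded genes of oxidative phosphorylation were both lower in Schisandrin B, with log2 fold changes of -1.27 for GPX4 and -1.02 for the median of the list. With the trend on GC content and transcript length removed, GPX4 was at -1.19 and the list median at -0.96, both past the threshold, which argues against that trend as the whole cause. Scaled by library totals alone, the values were -1.22 and -0.98. The larger share of mitochondrial counts lowered the share left to all other genes by -0.039 on the log2 scale, which argues against that share as the cause. The other 17 selenoproteins had a median of -0.12 with an SD of 0.78, which lies 1.15 above GPX4 and argues against a fall of that class as a whole. An effect of the treatment, which the design names, may explain the fall and stays open as a hypothesis found and tested on the same data.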

How the results depend on the processing

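The correction for GC content and transcript length was the 1 test here chosen only after the results were seen. Across the up to 16 alternatives run on single genes, 1926 values of the 122 named genes kept their direction and side of the threshold, 8 lost the call and 5 reversed, all 5 in FTL, which was never called. Of the list tests, run under up to 18 alternatives, 510 kept both, 28 lost a call, 12 gained one and 21 reversed. Gene counts with 1 library left out ran from 5284 to 5423 higher and 5332 to 5414 lower, and DESeq2 gave 4577 and 5225. The log2 fold changes of genes tested under both settings shifted by a median of 0.08 at most (stricter filter), and by 0.06 with upper-quartile factors. With an estimated correlation 0 lists were higher and 2 lower, and G2/M (median -2.06) lost its call at an adjusted p of 0.123. Fry called 18 lists higher, among them ferroptosis suppressors (0.037, adjusted p 6.46e-05) and drivers (0.23, adjusted p 3.52e-05), since it compares a list with no other genes. Over the 16 settings tested with camera and its preset correlation, the adjusted p ran from 0.266 to 0.812 for suppressors, with medians from -0.0028 to 0.27, from 0.188 to 0.486 for drivers, and up to 1.99e-14 for G2/M. Fry also reversed the direction for fatty acid synthesis (-0.064), p53 targets (-0.14), hypoxia (0.28) and islet genes (0.34). At least 5 CPM left 1238 genes higher and 882 lower by 2-fold, from fewer genes tested, and gave fatty acid synthesis 0.018, p53 targets -0.070 and FTL 0.057. FTL was 0.038 with upper-quartile factors, 0.019 with library totals and 0.037 with the GC and length trend removed. Fatty acid synthesis was -0.021 with library totals, -0.062 with voom and -0.036 with the GC and length trend removed. No filter gave iron handling 0.011, hypoxia 0.26, EMT 0.14, metallothioneins 0.10 and islet genes 0.29. DESeq2 gave iron handling -0.063, EMT 0.075, metallothioneins -0.029 and islet genes 0.18, and voom gave hypoxia 0.27 and islet genes 0.33. With 1 library left out, fatty acid synthesis ran from -0.097 to -0.053 and FTL from -0.064 to 0.023. For these reversals the cause was not tested. A reversed list can keep the sign of its median where the test's direction changed. With a replicate block 5471 genes were higher and 5504 lower, 10853 of 11073 calls were kept, and xenobiotic targets and autophagy lost their calls at an adjusted p of 0.0592. The 3 alternatives planned for normalized values alone were not run, because counts were used.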

Other observations

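The 5 lists of this paragraph and the next, and the genes named from them, were chosen only after the results were seen, as were their tests. Genes of the ER translocon and of N-glycosylation rose in 28 of 32 cases and fell in 1, with a median log2 fold change of 0.88 (camera adjusted p = 1.92e-07, adjusted p = 0.211 with an estimated correlation). SEC61A1, the channel subunit, rose 2.69-fold, SEC63 2.94-fold and STT3A, an oligosaccharyltransferase subunit, 2.03-fold, while OST4 fell 2.05-fold. Tubulin, actin and associated genes fell in 24 of 25 cases, with a median of -1.06 (camera adjusted p = 1.02e-09, adjusted p = 0.0954 with an estimated correlation). ACTB, often used as a reference gene, fell 2.43-fold, TUBA1B 2.96-fold and TUBB3 3.21-fold. Tubulin genes have close paralogs, so single members are uncertain.

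Cytosolic tRNA synthetases rose in 10 of 20 cases and fell in 6 (camera adjusted p = 0.174), with GARS1 at 2.65-fold higher. Mitochondrial tRNA synthetases fell in 13 of 16 cases and rose in 1, with a median of -0.50 (camera adjusted p = 9.65e-04, adjusted p = 0.0954 with an estimated correlation), and LARS2 fell 2.24-fold. Selenoprotein genes other than GPX4 split evenly, with 7 higher and 7 lower of 17 (camera adjusted p = 0.783). Their median of -0.12 was negative while the mean of 0.08 and the test's direction were positive. SELENOS, of the ER membrane, rose 3.11-fold and GPX3 fell 2.65-fold.

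The lncRNA genes took a 1.90-fold larger share of counts in Schisandrin B. NEAT1 and MALAT1, nuclear RNAs named after their values were seen, rose from 616 to 4523 and from 171 to 922 CPM. At matched expression lncRNAs lay 0.39 above protein-coding genes on the log2 scale, with 0.11 to 0.89 over 10 bins. A large difference had been set in advance as evidence against a lower yield of protein-coding RNA with lncRNA unchanged. That was mistaken, because such a yield also places lncRNAs higher, and the test was read anew only after the result was seen. A uniform lower yield needs a difference of 0.95. The bin of highest expression had 0.89, and all 10 bins lay below 0.95. The SD of 1.07 is between single lncRNAs, and a median over a bin of the 2453 tested varies far less. The matched difference of 0.39 and the lowest bin of 0.11 argue against a uniform lower yield as the whole cause. A yield that differs between genes was not tested. The share of rRNA genes was also larger, 0.00664% in Schisandrin B against 0.00049% in vehicle (exact permutation p = 0.1, n = 3 each), and all 8 tested rRNA genes rose. The far larger share of mitochondrial rRNA was 0.62% against 0.576% (exact permutation p = 0.3). A difference between the groups in which RNA entered the libraries stays open. The 10 lncRNAs with the largest gain gave 50.8% of the summed gain, so they account for part of it. Whether a few abundant lncRNAs are its main source stays open. As a marker of genomic DNA, 859 olfactory receptor genes had 207 counts in vehicle and 329 in Schisandrin B. Their summed CPM ratio was 1.68 with a 95% interval of 1.41 to 2.01, which includes the lncRNA fold. That ratio alone cannot tell DNA from a treatment effect. The amounts, compared only after the result was seen, were small. All 859 genes together had 3.98 to 4.98 CPM in vehicle libraries and 5.92 to 9.37 in Schisandrin B libraries. The lncRNA share rose from 1.69% to 3.21% of counts, and the smallest gain among those 10 lncRNAs was 136 CPM. These amounts argue against DNA spread evenly over genes as the main source of the gain. Gene length was not matched.

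The 6 libraries can be split 10 ways into groups of 3, which is too few for a share under 0.05. The real split called 5527 genes higher, 5546 lower, 2331 and 1380 of them by at least 2-fold, and 1 split of 10 reached each of these counts. The highest count in any other split was 0 with edgeR, where 48 to 83 genes had an unadjusted p under 0.05 against 11415 in the real split. Every other split mixes libraries of both treatments in each group. The difference between treatments then widens the spread within the groups, so few genes could be called. These counts of 0 therefore say nothing about chance. No other tool was run on the splits. For the lists, 8 were higher and 8 lower in the real split. A split and its mirror image count as 1, so either direction of another split was compared with each of these numbers. The highest of the other splits was then also 8, and 2 splits reached that number.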
